A study of Pseudomonas putida with 8 samples.

How the data were processed

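RNA sequencing was done on 8 libraries of Pseudomonas putida LS46, in 4 groups of 2 biological replicates per the series design text. Total RNA was isolated with a spin-column kit and made into Illumina libraries with a 300 bp size selection, per the labels' protocols. CASAVA 1.8 is named in the submitters' processing notes; the aligner, the counting tool, the genome build, strand use and filters are not given in the sources used here. Without stated strand use, reads of a gene and of an overlapping or antisense neighbour cannot be told apart, and reads shared by near-identical genes may have been split.

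The deposited files hold log2 values, 1 per gene and library, that the authors made. Below a log2 value of 5.5, 100% of the deposited log2 values in every library equalled the log2 of a whole number within 0.005, where 8.2% would do so by chance, and column totals differed between libraries. They were therefore read as the log2 of whole read counts rounded to 2 decimals, with no depth or length scaling, and turned back into reads. The rounding leaves reads of abundant genes known only to within the rounding step. Blank entries, 175 in all, were taken as 0 reads; in 170 of them the other replicate had at most 5 reads and in none more than 13. Between 457 and 463 rows per file repeated another row exactly, and each locus tag was used once. Files listed between 4567 and 4584 tags, 4807 tags appeared in any library and 4224 in all 8. A tag not listed for a group was treated as missing and not as 0, so a gene was tested only where both groups listed it. Genes are named by locus tag and by the product text in the files. No tag matched the table of gene names for another strain of the species, so no coordinates are given.

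Reads were scaled to CPM, reads relative to a fixed total, with trimmed mean of M values factors (30% trimmed on M, 5% on A), recomputed over the tags in all 8 libraries; factors ran from 0.821 for a waste fatty acid library to 1.33 for a stationary library. CPM values in the text carry this scaling. Genes with at least 1 CPM in at least 2 libraries were kept, and 52 genes listed in both groups of each comparison fell below this filter. The design written before the data were examined foresaw a negative binomial count test for counts. The deposited unit is log2, but the reads recovered from it could have taken that count test, so the choice made here departs from the plan. In its place limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend, on log2(CPM + 1), with group as the only term over all 8 libraries. This leaves 4 residual degrees of freedom per gene, to which the trend prior added 6.55. Fold changes are on the log2(CPM + 1) scale and understate the change of genes near 1 CPM. P-values were adjusted by Benjamini-Hochberg within each comparison, and adjusted p under 0.05 counted as past the threshold. All adjusted p-values for genes are limma's. The 4 comparisons were waste against pure glycerol, waste fatty acids against pure glycerol, waste fatty acids against waste glycerol, and stationary against exponential waste glycerol.

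Gene lists, 23 tested, were fixed as word patterns before the data were examined. After the product texts had been read, and before any fold change was computed, members that the patterns had missed or wrongly taken were added or dropped. The lists as first written gave 5, 6, 8 and 7 called lists against 6, 8, 10 and 7. The PHA and glycerol lists then had 2 members each in all 8 libraries, under the minimum of 3, and were not tested, so their calls rest on the added members. Lists were tested with limma's camera with a preset correlation of 0.01 over genes listed in all 8 libraries, adjusted over the 23 lists within a comparison. No list passed in any comparison with an estimated correlation, and that adjusted p stands beside each call. Named genes follow a rule written before the data were examined. It takes a fixed set of PHA, glycerol, fatty acid and glyoxylate genes. It adds the 5 rising and 5 falling annotated genes with the largest change, at 5 CPM or more in the higher group and with no overlap between replicates. It also takes up to 3 such members of each list past camera or with at least 50% of its members past the threshold, and the text names a part of these. Of the fixed set, the PHA depolymerase and PhaG were not compared here.

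The method was tested on simulated reads drawn with the spread averaged over all groups, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. The wider spread of the stationary replicates was therefore not simulated. Of genes changed 1.5-fold, 49.3%, 55.2%, 49.3% and 47.8% were recovered in the 4 comparisons in the order above, over 4333, 4325, 4507 and 4309 simulated genes tested. For 2-fold changes the shares were 98.5%, 94.0%, 98.5% and 97.0%, and for 4-fold changes 100% in each. False calls made up 3.51%, 7.26%, 6.25% and 2.98% of calls. These shares hold for that equal spread and for few changed genes, while in the data 33.9% to 66.4% of genes passed. A simulated list of 30 genes raised 1.5-fold was called in each comparison, and none of 20 unchanged lists was, over 3860 genes. Simulated genes varied independently, so this cannot tell whether the preset correlation is high enough for real lists.

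Alternatives planned before the data were examined were median-of-ratios size factors, quantile normalization, limma without the trend, no filter, pseudocounts of 0.1 and 5, the 4 compared libraries alone, a replicate block, leaving out each library, a 2-fold minimum and a 0.01 threshold; for lists, an estimated correlation, fry and the block. Scaling by total reads, voom weights, the tags in all 8 libraries, lists as first written, list tests without each library, and thinning to the shallowest library were added after the files had been seen. The planned count-based alternatives were not run either, which also departs from the plan. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.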

Results

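The transcriptome of Pseudomonas putida LS46 was measured by RNA sequencing of total RNA. LS46 is a wild-type strain that makes medium chain length polyhydroxyalkanoate (PHA), a polyester that bacteria store as intracellular granules. Cells grew in a defined mineral medium with pure glycerol, with waste glycerol from biodiesel production, or with waste free fatty acids as the carbon source. The 8 libraries fell into 4 groups with 2 biological replicates each. Exponential cells were sampled at 8 h on pure glycerol, on waste glycerol and on waste fatty acids, and stationary cells at 32 h on waste glycerol. Glycerol was supplied at the equivalent of 30 g/L and fatty acids at 1% by volume.

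Total reads over the listed genes were 9771579 and 9577431 for pure glycerol, 8317494 and 7933472 for exponential waste glycerol, and 7910583 and 8141342 for waste fatty acids. The stationary libraries were shallower, with 4872459 and 5998653 reads. An OmpF family protein (PPUTLS46_004174), an outer membrane porin, took the largest share in the exponential libraries, from 2.02% to 2.54% of reads. In the stationary libraries the largest share, 1.38% and 1.40%, belonged to 30S ribosomal protein S1 (PPUTLS46_015469).

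Replicates lay close together and groups lay apart. Replicate libraries correlated across genes at r = 0.997 for pure glycerol, 0.997 for exponential waste glycerol, 0.996 for waste fatty acids and 0.983 for stationary waste glycerol. Genes are not independent replicates, so these values describe likeness only. The chi-square of reads per degree of freedom was 6.60, 4.61 and 5.11 in the 3 exponential pairs and 16.8 in the stationary pair, so no pair was 1 library counted again. Principal component 1 held 54.2% of the variance over 4172 genes and separated both glycerol groups at 8 h from the other groups, while component 2 held 29.7%.

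**Figure D1:**
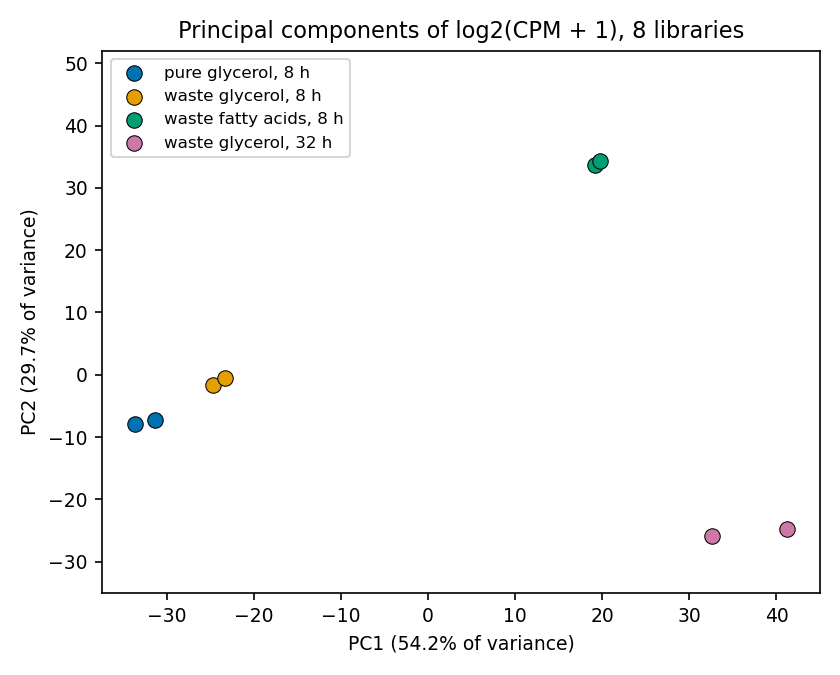
Each point is 1 library, placed by its scores on principal components 1 (x axis, 54.2% of variance) and 2 (y axis, 29.7%) of log2(CPM + 1) over 4172 genes, with colours for the 4 groups. The pure and waste glycerol libraries at 8 h lie together on component 1, from -33.6 to -23.3, and waste fatty acids and stationary waste glycerol lie at 19.2 or above.

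Waste glycerol was compared with pure glycerol at 8 h, which asks how the crude substrate changes expression in growing cells. On waste glycerol, a copper resistance protein of the CopA family (PPUTLS46_023578) rose 4.72-fold, from 342.2 ± 98.9 to 1586 ± 6.59 CPM (SD, n = 2). The PHA synthase (PPUTLS46_005621), which polymerises hydroxyacyl-CoA into PHA, fell from 1074 ± 51.4 to 563.0 ± 32.6 CPM. Glycerol kinase (PPUTLS46_022201), which phosphorylates glycerol on entry, fell from 4006 ± 43.9 to 1853 ± 37.6 CPM, and the RNA polymerase sigma factor RpoS (PPUTLS46_014694), the regulator of the general stress response, fell from 2974 ± 54.8 to 1485 ± 28.0 CPM. Of 4338 genes tested with limma, 774 were higher and 695 lower at an adjusted p under 0.05, and 165 and 131 of these differed at least 2-fold.

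The genes with the largest rises were an acyl-CoA dehydrogenase (PPUTLS46_000700, log2 fold change 4.06, SE 0.12, adjusted p = 9.6e-09) and a 3-hydroxybutyryl-CoA epimerase of the fatty acid oxidation family (PPUTLS46_000695, 4.01). A class II aldolase (PPUTLS46_000640, 3.91), a Bcr/CflA family drug transporter (PPUTLS46_023313, 3.83) and an LrgB family protein (PPUTLS46_013058, 3.29) followed. The 5 named falls included pyruvate dehydrogenase (PPUTLS46_023483, -3.96, SE 0.18, adjusted p = 1.6e-07), transketolase (PPUTLS46_023488, -3.73) and the acetoin dehydrogenase E2 subunit (PPUTLS46_023493, -3.49). These 3 carry neighbouring locus tags, beside that of an ATP-NAD/AcoX kinase (PPUTLS46_023478). The names pyruvate dehydrogenase and transketolase are product texts, and these genes may encode other subunits of acetoin dehydrogenase. A cobalamin synthesis protein (PPUTLS46_016814, -3.54) and a quinoprotein ethanol dehydrogenase (PPUTLS46_019281, -3.42), an alcohol-oxidising enzyme that uses pyrroloquinoline quinone (PQQ), also fell.

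Among 31 measured heavy metal resistance genes, 13 rose and 2 fell, and 16 passed when adjusted over the list alone. The risers included copper resistance B (PPUTLS46_023588, log2 fold change 2.06) and a heavy metal translocating P-type ATPase (PPUTLS46_023328, 1.73). The list rose as a set (camera adjusted p = 0.0177), and the adjusted p was 0.440 with an estimated correlation. Of 4 PHA genes none rose and 3 fell, with 3 passing when adjusted over the list alone. They were the synthase, PhaF (PPUTLS46_005601, -0.80) and a granule-associated protein (PPUTLS46_005596, -0.89). Both of the last bind the granule surface. In camera the set had adjusted p = 0.0278, and adjusted p = 0.440 with an estimated correlation.

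Type VI secretion, a contractile apparatus for injecting proteins into other cells, had 12 of 45 genes higher and none lower, and 12 adjusted over the list alone. The protein of the VC_A0110 family (PPUTLS46_003542) rose from 90.0 ± 0.572 to 274.7 ± 11.9 CPM. For this set camera gave adjusted p = 0.0278, and adjusted p = 0.795 with an estimated correlation, while fry gave 0.0610. Sodium/proton antiporters had 5 of 14 genes higher and none lower (6 adjusted over the list alone), led by a sodium/hydrogen exchanger (PPUTLS46_005771, 1.22). Phosphate starvation genes had 5 of 13 higher and 1 lower (8 adjusted over the list alone), led by the substrate-binding protein of a phosphate ABC transporter (PPUTLS46_019371, 2.13). Both sets had a camera adjusted p = 0.0350, adjusted p = 0.440 with an estimated correlation, and adjusted p = 0.0718 after quantile normalization. The phosphate set had adjusted p = 0.0627 without pure glycerol replicate 2.

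In the list for stationary phase and oxidative stress, 1 of 19 genes rose and 7 fell, with 9 adjusted over the list alone. RpoS and a universal stress protein (PPUTLS46_019431, -1.17) fell, and a Dps family ferritin (PPUTLS46_006356, 1.05) rose, to 48.8 and 29.9 CPM. A more abundant Dps family ferritin (PPUTLS46_021556) was lower on waste glycerol, at 1118 and 1117 CPM against 2019 and 1920 CPM. The set test gave adjusted p = 0.0450, adjusted p = 0.440 with an estimated correlation, and adjusted p = 0.0718 after quantile normalization. Without pure glycerol replicate 1 it was 0.0767, and without waste glycerol replicate 2 it was 0.0705. For the 17 other lists the camera adjusted p ran from 0.0703 to 0.967.

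Among 36 beta-oxidation genes 7 rose and 8 fell (15 adjusted over the list alone), and the set did not pass (camera adjusted p = 0.729). The fatty acid oxidation complex (PPUTLS46_004399), which carries out the middle steps of beta-oxidation, rose (0.62), as did 3-ketoacyl-CoA thiolase (PPUTLS46_004404, 0.50) and isocitrate lyase (PPUTLS46_012430, 0.52), the entry enzyme of the glyoxylate shunt. The MIP family channel (PPUTLS46_022196), of the family of glycerol facilitators, fell (-0.41). Glycerol-3-phosphate dehydrogenase (PPUTLS46_022211) had a log2 fold change of 0.15 (SE 0.13, adjusted p = 0.44) and did not pass. It passed after quantile normalization (0.40, adjusted p = 0.00364), with total reads alone (0.27, adjusted p = 0.0119) and with only the 4 libraries compared (0.14, adjusted p = 0.0485). A fit on only the 4 libraries compared, without the stationary pair in its spread, gave 1178 higher and 1093 lower genes. Without any 1 of these 4 libraries, the counts fell to between 454 and 495 higher and between 353 and 431 lower, and the channel lost its call in each of these 4 fits (adjusted p from 0.0526 to 0.0947), the lyase and the thiolase in 2 each. Scaling by total reads alone gave 1237 higher and 570 lower genes, with a median log2 fold change of 0.12 over all genes in place of 0.01, and took the type VI and phosphate sets to adjusted p = 0.109.

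**Figure D2:**
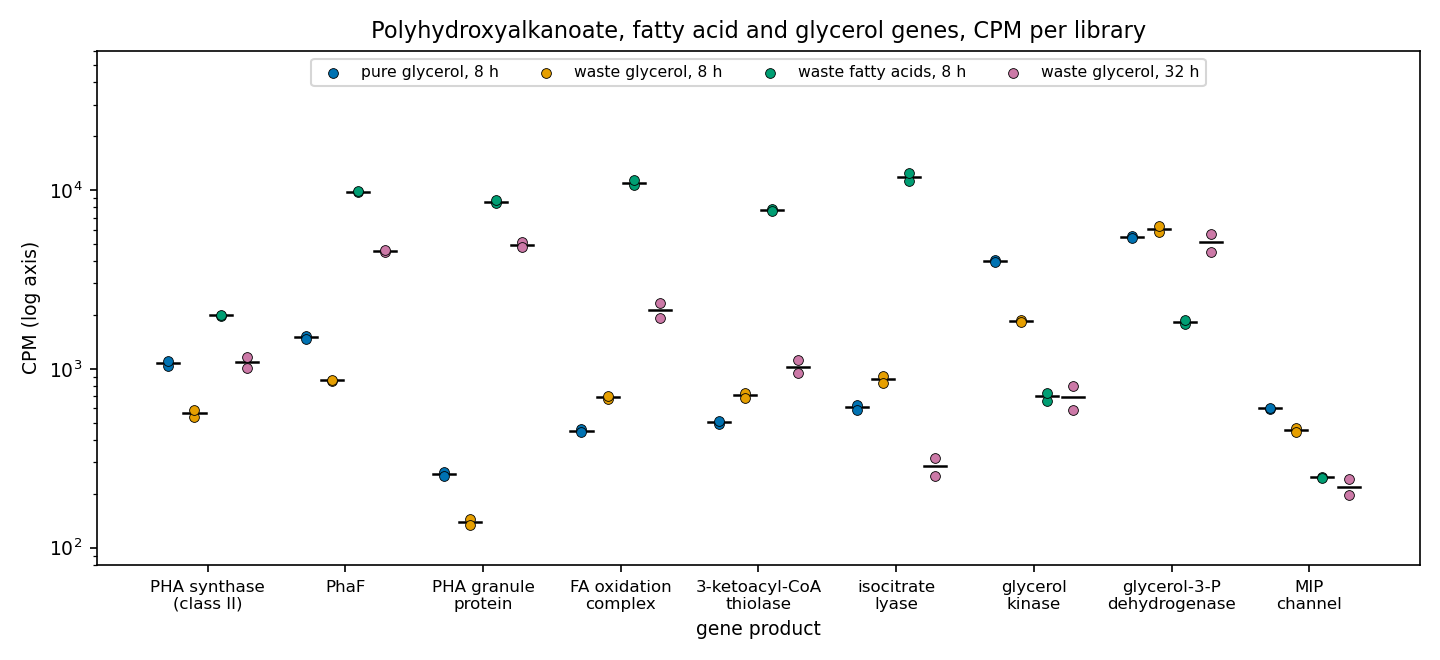
CPM per library (y axis, log scale) for 9 genes of PHA, fatty acid and glycerol metabolism (x axis), with 1 point per library, 2 libraries per group, colours for the groups and a bar at the group mean. The granule-associated protein lies at 8593 CPM on waste fatty acids and 4932 CPM in stationary waste glycerol, against 258.4 on pure and 138.8 on waste glycerol at 8 h.

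Waste fatty acids were compared with pure glycerol at 8 h. An acetyl-CoA acetyltransferase (PPUTLS46_012993), a thiolase of acetoacetyl-CoA metabolism, rose 139-fold on fatty acids, from 30.7 ± 1.93 to 4401 ± 4.44 CPM (SD, n = 2). The fatty acid oxidation complex rose 24.4-fold to 10993 ± 420 CPM, 3-ketoacyl-CoA thiolase 15.4-fold to 7717 ± 159 CPM, and isocitrate lyase 19.3-fold to 11791 ± 797 CPM. The granule-associated PHA protein rose 33.1-fold to 8593 ± 202 CPM, and the PHA synthase 1.86-fold to 1997 ± 17.6 CPM. Glycerol kinase fell from 4006 ± 43.9 to 699.7 ± 50.7 CPM. Of 4338 genes tested with limma, 1255 were higher and 1301 lower, and 481 and 406 of these differed at least 2-fold.

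Other large rises were in a class III aminotransferase (PPUTLS46_024428, log2 fold change 6.07, SE 0.10, adjusted p = 3.1e-11), the B subunit of 3-oxoacid CoA-transferase (PPUTLS46_007649, 5.95), which activates acetoacetate, and the sugar porin OprB (PPUTLS46_017699, 5.10). An acyl-CoA dehydrogenase (PPUTLS46_024448, 3.59), the entry step of beta-oxidation, reached 15650 ± 323 CPM. The largest falls were in a gene annotated as pyruvate dehydrogenase (PPUTLS46_023483, -6.41, SE 0.18, adjusted p = 4.3e-10) and an RND efflux outer membrane lipoprotein (PPUTLS46_018286, -6.17). The tag of the first lies in the run of acetoin dehydrogenase genes, so it may encode a subunit of that enzyme. The iron-sulfur and FAD-binding subunits of glycolate oxidase (PPUTLS46_026211, -6.10, and PPUTLS46_026206, -6.09) and a putative glucose dehydrogenase subunit (PPUTLS46_009009, -6.06) also fell. Other genes annotated as glucose dehydrogenase did not fall with it. PPUTLS46_017694 stood at 2637 and 2670 CPM against 197.9 and 197.7 on pure glycerol, and PPUTLS46_014089 at 503.0 and 513.0 against 490.8 and 473.4.

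All 4 measured PHA genes rose, and 4 passed when adjusted over the list alone (camera adjusted p = 0.00375, and adjusted p = 0.418 with an estimated correlation). PhaF rose from 1503 ± 38.6 to 9767 ± 85.9 CPM. All 3 glycerol genes fell, and 3 passed when adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.690 with an estimated correlation). Their log2 fold changes were -2.52 for glycerol kinase, -1.57 for glycerol-3-phosphate dehydrogenase and -1.28 for the MIP channel. Among 36 beta-oxidation genes 12 rose and 8 fell (20 adjusted over the list alone), and the set did not pass (camera adjusted p = 0.221).

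Nitrogen assimilation genes had 18 of 35 members higher and 6 lower, with 24 adjusted over the list alone. The large subunit of glutamate synthase (PPUTLS46_025013, 4.60), the urease accessory protein UreD (PPUTLS46_018586, 4.56) and the urease gamma subunit (PPUTLS46_018581, 4.37) led them. Urease releases ammonia from urea. In camera the set had adjusted p = 0.0162, and adjusted p = 0.690 with an estimated correlation. Type VI secretion had 17 of 45 genes higher and 4 lower (21 adjusted over the list alone). Its Hcp1 family effector (PPUTLS46_003497) rose from 1148 ± 96.9 to 6225 ± 128 CPM. The set gave adjusted p = 0.00923, and adjusted p = 0.792 with an estimated correlation.

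Ribosomal proteins had 29 of 48 genes higher and 6 lower, and 37 passed when adjusted over the list alone. S21 (PPUTLS46_024348, 1.94) and S20 (PPUTLS46_001857, 1.89) rose most. For this set camera gave adjusted p = 0.00375, adjusted p = 0.792 with an estimated correlation, and adjusted p = 0.166 after quantile normalization.

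Chaperones and proteases moved the other way, with 4 of 23 genes higher and 15 lower (19 adjusted over the list alone). GroEL (PPUTLS46_013648), which folds newly made proteins, fell from 7623 ± 718 to 1954 ± 199 CPM, and its partner GroES (PPUTLS46_013643) had a log2 fold change of -1.97. ClpB (PPUTLS46_003532, 2.01) rose, and its locus tag lies among those of the type VI genes. The set gave adjusted p = 0.00375, and adjusted p = 0.792 with an estimated correlation. In the PQQ and one-carbon list, 1 of 15 genes rose and 10 fell (11 adjusted over the list alone). The quinoprotein ethanol dehydrogenase fell from 1813 ± 433 to 48.0 ± 11.3 CPM. The set gave adjusted p = 0.00772, and adjusted p = 0.792 with an estimated correlation.

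Compatible solute genes, which serve osmotic balance, had 3 of 29 members higher and 13 lower, with 16 adjusted over the list alone. A choline ABC transporter permease (PPUTLS46_024828) fell from 102.4 ± 1.10 to 36.4 ± 1.59 CPM, and glycine betaine/L-proline transporter genes (PPUTLS46_024823, -1.86, and PPUTLS46_024833, -1.76) fell with it. The set test gave adjusted p = 0.0162, and adjusted p = 0.418 with an estimated correlation. The 15 other lists had camera adjusted p from 0.0540 to 0.963. Scaling by total reads alone gave 959 higher and 1670 lower genes, with a median log2 fold change over all genes of -0.18 in place of -0.01.

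The waste streams were compared directly, fatty acids against glycerol, both at 8 h, and this is also the test of the difference between the comparisons above. The acetyl-CoA acetyltransferase was 102-fold higher on fatty acids and the granule-associated PHA protein 61.5-fold higher, at 8593 ± 202 against 138.8 ± 6.89 CPM (SD, n = 2). The fatty acid oxidation complex was 15.8-fold, isocitrate lyase 13.5-fold and the PHA synthase 3.55-fold higher. CopA (PPUTLS46_023578) was 32.6-fold lower on fatty acids, at 47.7 ± 0.186 against 1586 ± 6.59 CPM. Of 4515 genes tested with limma, 1289 were higher and 1378 lower, and 430 and 418 of these differed at least 2-fold.

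The class III aminotransferase (log2 fold change 5.88, SE 0.10, adjusted p = 3.1e-11), the 3-oxoacid CoA-transferase subunit (5.70) and a fusaric acid resistance protein (PPUTLS46_013188, 5.40) rose with these. The other large falls were in LrgB (-5.12, SE 0.34, adjusted p = 5.4e-07) and LrgA (PPUTLS46_013053, -4.70) family proteins, the glycolate oxidase iron-sulfur subunit (-4.68) and the RND efflux lipoprotein (-4.54).

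Ribosomal proteins had 31 of 49 genes higher on fatty acids and 2 lower, with 35 adjusted over the list alone, led by L28 (PPUTLS46_017429, 1.54). In camera the set had adjusted p = 3.1e-05, adjusted p = 0.693 with an estimated correlation, and adjusted p = 0.886 after quantile normalization. Of 36 genes for ATP synthase and the respiratory chain, 21 were higher and 7 lower (28 adjusted over the list alone). Cyanide-insensitive ubiquinol oxidase subunit I (PPUTLS46_012918, 3.18) and cytochrome o ubiquinol oxidase subunit II (PPUTLS46_004072, 2.82), both terminal oxidases, led them. That set gave adjusted p = 0.00736, adjusted p = 0.693 with an estimated correlation, and adjusted p = 0.190 after quantile normalization.

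PHA genes had 4 of 5 members higher and none lower, with 4 adjusted over the list alone (camera adjusted p = 0.000876, and adjusted p = 0.296 with an estimated correlation). All 3 glycerol genes were lower, with 3 adjusted over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.505 with an estimated correlation). Glycerol-3-phosphate dehydrogenase stood at 1832 ± 61.0 CPM against 6046 ± 322. Nitrogen assimilation had 17 of 36 genes higher and 6 lower (23 adjusted over the list alone), among them an ammonium transporter (PPUTLS46_017814, 3.25). Its set gave adjusted p = 0.00676, and adjusted p = 0.451 with an estimated correlation. Its call held with total reads alone, where its median log2 fold change of 0.25 became -0.01 as the median over all genes fell by a like amount.

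Heavy metal resistance had 4 of 34 genes higher and 15 lower, with 19 adjusted over the list alone. Besides CopA, another CopA family gene (PPUTLS46_008599, -3.85) and a heavy metal transport protein (PPUTLS46_023318, -3.70) fell. For this set camera gave adjusted p = 0.00736, and adjusted p = 0.451 with an estimated correlation. In the PQQ and one-carbon list no gene rose and 13 of 17 fell (14 adjusted over the list alone), among them formate dehydrogenase subunit alpha (PPUTLS46_023838, -1.51). That set gave adjusted p = 0.00736, and adjusted p = 0.565 with an estimated correlation.

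Compatible solute genes had 2 of 30 members higher and 15 lower (16 adjusted over the list alone), with adjusted p = 0.00736, and adjusted p = 0.296 with an estimated correlation. Chaperones and proteases had 7 of 25 higher and 15 lower (22 adjusted over the list alone), with adjusted p = 0.0125, and adjusted p = 0.693 with an estimated correlation. The protease subunit HslU (PPUTLS46_005631) fell from 678.4 ± 6.18 to 192.6 ± 6.34 CPM. Sodium/proton antiporters had 1 of 15 higher and 11 lower (12 adjusted over the list alone). The set gave adjusted p = 0.0314, adjusted p = 0.451 with an estimated correlation, and adjusted p = 0.108 after quantile normalization. The 13 other lists had camera adjusted p from 0.0554 to 0.943. Scaling by total reads alone gave 786 higher and 2056 lower genes, with a median log2 fold change over all genes of -0.27 in place of -0.01.

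**Figure D3:**
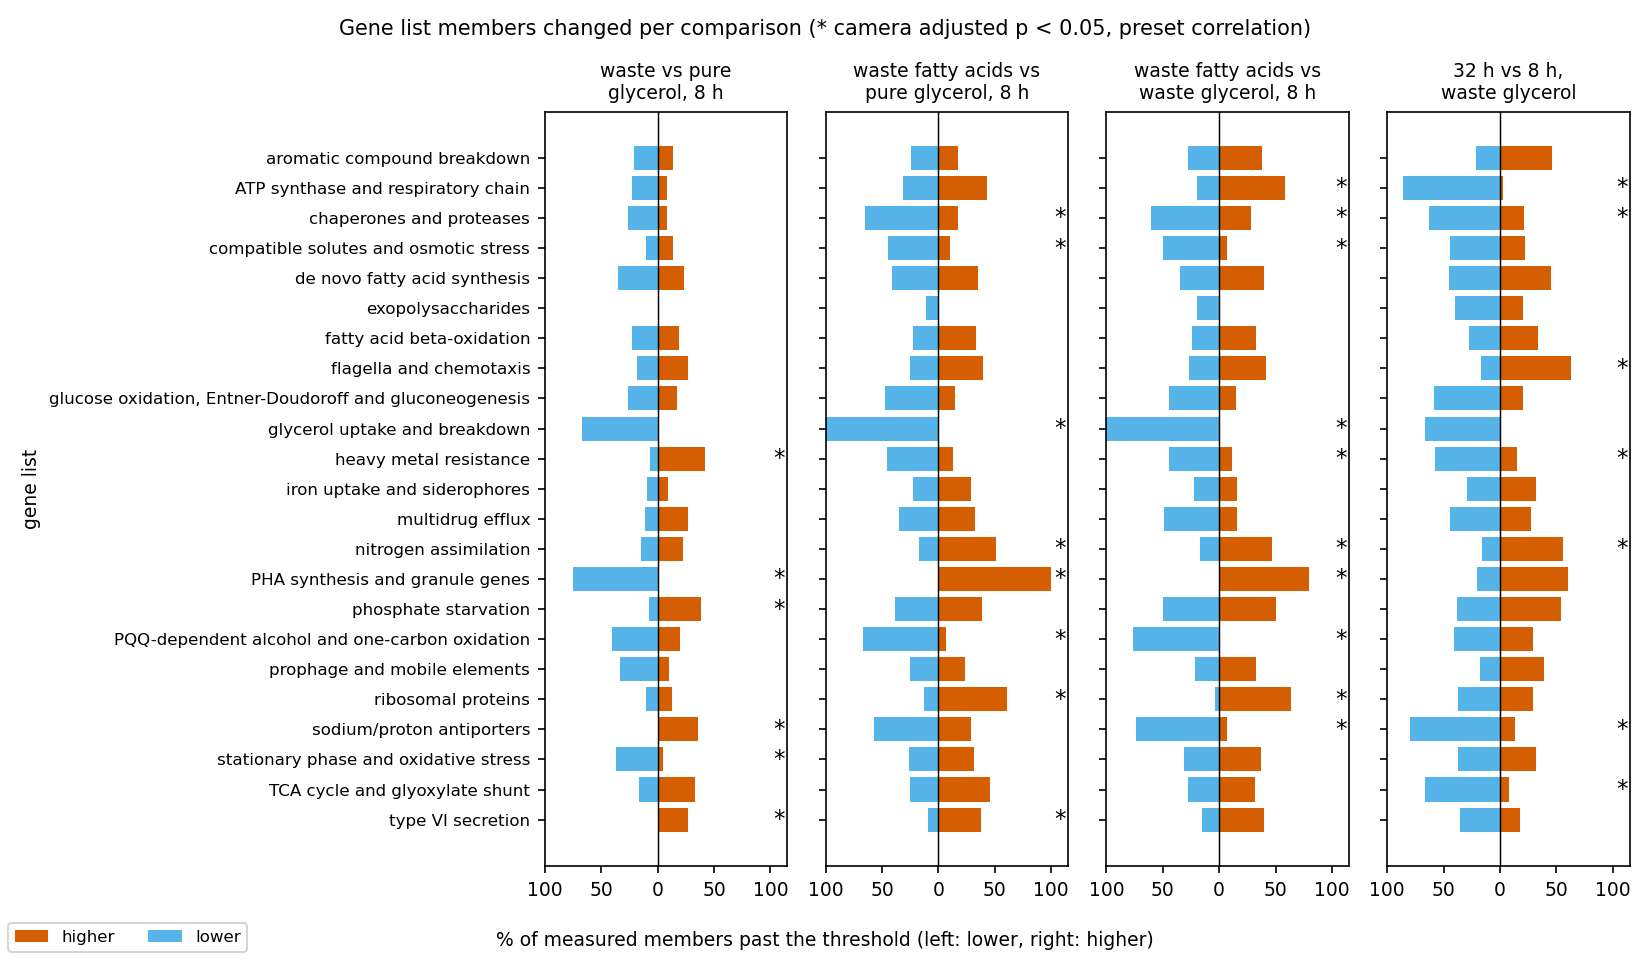
For each of 23 gene lists (rows) and 4 comparisons (panels), bars give the percentage of measured members past the threshold (x axis), higher to the right and lower to the left, and a star marks lists past camera with the preset correlation. In the stationary panel, 30 of 35 genes for ATP synthase and the respiratory chain are lower and 1 is higher.

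Stationary cells at 32 h were compared with exponential cells at 8 h, both on waste glycerol. Genes for using nitrite, a nitrogen source once reduced to ammonium, were among those that rose most. The nitrite transporter (PPUTLS46_004189) rose 56.9-fold, from 5.74 ± 0.349 to 383.4 ± 47.1 CPM (SD, n = 2), and the large subunit of nitrite reductase (PPUTLS46_015084) 39.3-fold, from 17.7 ± 0.399 to 737.6 ± 120 CPM. The beta subunit of ATP synthase (PPUTLS46_016679) fell from 7186 ± 111 to 815.9 ± 191 CPM. The granule-associated PHA protein rose from 138.8 ± 6.89 to 4932 ± 213 CPM, and the PHA synthase from 563.0 ± 32.6 to 1087 ± 107 CPM. Of 4316 genes tested with limma, 1418 were higher and 1446 lower, and 547 and 651 of these differed at least 2-fold. The fit gave all groups a shared spread, while the stationary replicates differed more than the exponential ones. Adjusted p-values of this comparison may therefore be too small, and those of the comparisons between exponential groups too large. With only the 4 libraries compared, 1279 genes were higher and 1333 lower.

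The other leading rises were in cyanate hydratase (PPUTLS46_010494, log2 fold change 6.53, SE 0.14, adjusted p = 2.6e-10), which breaks cyanate down to ammonia, a molybdopterin oxidoreductase (PPUTLS46_015079, 6.10) with a tag beside nitrite reductase, and a branched-chain amino acid ABC transporter (PPUTLS46_006431, 5.42). The leading falls were in the class II aldolase (-4.98, SE 0.28, adjusted p = 9.9e-08), CopA (PPUTLS46_023578, -4.49), the heavy metal transport protein (-4.38), catalase (PPUTLS46_023883, -3.97), which breaks down hydrogen peroxide, and the other CopA family gene (-3.92).

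Of 35 genes for ATP synthase and the respiratory chain, 1 rose and 30 fell, with 31 adjusted over the list alone. ATP synthase subunits epsilon (PPUTLS46_016684, -3.43) and alpha (PPUTLS46_016669, -2.60) were among them. The set test gave adjusted p = 3.4e-10, and adjusted p = 0.689 with an estimated correlation. Genes of the TCA cycle and glyoxylate shunt had 2 of 24 members higher and 16 lower (19 adjusted over the list alone). The 2-oxoglutarate dehydrogenase E1 component (PPUTLS46_019621) fell from 4098 ± 17.1 to 938.9 ± 206 CPM, and isocitrate lyase had a log2 fold change of -1.62. That set gave adjusted p = 0.00161, and adjusted p = 0.713 with an estimated correlation.

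Flagella and chemotaxis genes had 34 of 54 members higher and 9 lower, with 43 adjusted over the list alone. The rod protein FlgB (PPUTLS46_020521) rose from 432.3 ± 8.11 to 2245 ± 68.2 CPM, and the basal body protein FliE (PPUTLS46_020416) from 253.7 ± 12.2 to 1163 ± 58.2 CPM. The set gave adjusted p = 0.00222, and adjusted p = 0.713 with an estimated correlation. Nitrogen assimilation had 18 of 32 genes higher and 5 lower (23 adjusted over the list alone), with the nitrate-binding protein NasS (PPUTLS46_004199, 4.95) behind the nitrite genes. Its set gave adjusted p = 0.0111, and adjusted p = 0.689 with an estimated correlation.

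Sodium/proton antiporters had 2 of 15 genes higher and 12 lower (15 adjusted over the list alone), among them subunit D of a monovalent cation/H+ antiporter (PPUTLS46_007484, -2.87). In camera the set had adjusted p = 0.00238, and adjusted p = 0.689 with an estimated correlation. Heavy metal resistance had 5 of 33 genes higher and 19 lower (25 adjusted over the list alone), with adjusted p = 0.0111, adjusted p = 0.689 with an estimated correlation, and adjusted p = 0.0788 without stationary replicate 2. Chaperones and proteases had 5 of 24 higher and 15 lower (21 adjusted over the list alone), and GroEL fell from 4824 ± 50.8 to 1001 ± 263 CPM. That set gave adjusted p = 0.0219, adjusted p = 0.725 with an estimated correlation, and adjusted p = 0.132 after quantile normalization.

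PHA genes had 3 of 5 members higher and 1 lower (5 adjusted over the list alone), and the set did not pass (camera adjusted p = 0.0544). PhaF rose from 861.6 ± 3.57 to 4552 ± 93.8 CPM. The fatty acid oxidation complex (1.60) and 3-ketoacyl-CoA thiolase (0.53) rose, and glycerol kinase (-1.43) and the MIP channel (-1.05) fell. Glycerol-3-phosphate dehydrogenase stood at 5086 ± 849 CPM in stationary and 6046 ± 322 CPM in exponential cells, a log2 fold change of -0.26 (adjusted p = 0.11) that did not pass. Without stationary replicate 2 it was -0.43, in a fit with 1 stationary library and so no measure of stationary spread. Under quantile normalization or total reads the sign of the log2 fold change turned. Ribosomal proteins had 14 of 48 genes higher and 18 lower (32 adjusted over the list alone, camera adjusted p = 0.944). The 16 lists that did not pass had camera adjusted p from 0.0544 to 0.944. Scaling by total reads alone gave 1922 higher and 1148 lower genes, with a median log2 fold change over all genes of 0.31 in place of 0.06.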

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

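Scaling by total reads alone, voom weights, the tags in all 8 libraries, lists as first written, list tests without each library, and thinning were chosen after the data were seen. Over the named genes, 4516 of 4554 alternative values kept their direction and side of the threshold, 32 lost the call, 4 gained it and 2 changed sign. Most named genes were chosen in these data for large changes past the threshold without replicate overlap, so most could hardly lose their call. These counts therefore do not measure how stable the calls over all genes are. All gains and sign changes were glycerol-3-phosphate dehydrogenase. The sign changes were in stationary cells, at 0.00094 after quantile normalization and 0.0068 with total reads, and were not called. With total reads the median log2 fold change over all genes of that comparison also rose, from 0.06 to 0.31, so that sign change came with a shift over all genes. Otherwise the cause was not tested. Waste against pure glycerol moved most: 1178 higher and 1093 lower with its 4 libraries alone, 454 to 495 and 353 to 431 without each library (pure glycerol replicate 1 or 2, waste glycerol replicate 1 or 2), 510 and 448 at an adjusted p under 0.01, and 1237 higher with total reads. The lone library was assumed to vary like the other groups. For fatty acids against waste glycerol, total reads gave 786 higher. Requiring 2-fold, which keeps fewer genes by construction, left 165 and 131, 481 and 406, 430 and 418, and 547 and 651, in the order of the report. Of 6, 8, 10 and 7 lists called, an estimated correlation left 0 in each comparison (adjusted p from 0.296 to 0.795), and quantile normalization left 3 for waste against pure glycerol. Fry asks whether a list moves in 1 direction, without setting it against other genes. It called 8, 18, 18 and 18 lists, among them 5, 8, 10 and 7 of those called.

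The replicate numbers are not said to pair samples, and differences between replicates correlated between groups at -0.07 to 0.10. A replicate block gave 778 and 692, 1249 and 1289, 1287 and 1370, and 1425 and 1446 genes. It took the stationary and oxidative stress list on waste against pure glycerol to adjusted p = 0.0559. Thinned to the shallowest library, the comparisons gave 715 and 645, 1213 and 1222, 1250 and 1296, and 1365 and 1389 genes.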

Other observations

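All tests and gene runs in this part were chosen after the results had been seen, except 3 tests whose bounds were set before their values were known: both depth tests and the test of abundant genes. Several runs of neighbouring locus tags moved together, with most of their genes outside the lists. In stationary cells all 5 genes of a branched-chain amino acid transporter run (PPUTLS46_006411 to PPUTLS46_006431) rose, with log2 fold changes from 4.38 to 5.42, as did all 4 genes of the AapJ amino acid transporter run (2.46 to 2.97) and all 4 tested genes of a run with ureidoglycolate hydrolase (1.76 to 3.63), an enzyme of purine breakdown. In the same cells all 3 arginine deiminase pathway genes (-2.58 to -2.11), all 5 genes of a putrescine transporter run (-2.74 to -2.18) and all 5 genes of a run of spore coat U and pili products (-2.90 to -2.49) fell. The spore coat U run also fell in all 5 genes on waste fatty acids against pure glycerol (-2.46 to -1.62).

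On waste against pure glycerol, all 11 genes of the run around the quinoprotein ethanol dehydrogenase (PPUTLS46_019266 to PPUTLS46_019316) fell, with log2 fold changes from -3.42 to -2.18, and all 11 fell on fatty acids against pure glycerol (-5.21 to -3.83). All 6 genes of the acetoin dehydrogenase run (PPUTLS46_023473 to PPUTLS46_023498) fell in both comparisons too (-3.96 to -1.75, and -6.41 to -2.88). A run with a benzoate transporter and the class II aldolase rose in all 4 genes on waste glycerol at 8 h (2.05 to 3.91) and fell in all 4 at 32 h (-4.98 to -1.91). A run with a fusaric acid resistance protein and an RND efflux lipoprotein rose in all 4 genes on fatty acids against pure glycerol (3.85 to 4.81), and its 4 genes on waste against pure glycerol did not pass (-0.65 to 0.10). Without stated strand use or coordinates, reads running on into a neighbour stay possible in such runs.

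The fatty acid response at 8 h and the stationary response on waste glycerol overlapped, although the comparisons share no library. Of 4172 genes tested in both, 665 were higher in both against 394.8 for independent lists and 741 were lower in both against 413.3, while 243 and 180 moved opposite ways; the log2 fold changes correlated across genes at r = 0.405. In both comparisons the group in the numerator was sequenced less deeply, and thinning all libraries to 1 depth left r = 0.403, which argues against depth as the cause. Slower growth in both stays open. The ribosomal protein medians were above 0 under each scaling, lowest at 0.230 on fatty acids and 0.03 in stationary cells. They did not fall even in cells labelled stationary, so they cannot tell whether growth was slower on fatty acids. Bootstrap intervals, which resample genes and not cultures, include 0 after quantile normalization on fatty acids (-0.11 to 0.40) and under each scaling in stationary cells. Nitrogen shortage in both also stays open: 11 of 31 nitrogen assimilation genes were higher in both, where pairing the list's own 16 and 18 calls at random gives 9.29 (one-sided Fisher's exact test, p = 0.189, members not independent). That test takes the calls of each comparison as given, so it asks only whether the same members rose, not whether nitrogen was short. Random lists of 31 genes had a mean of 4.91 higher in both. As the nitrogen list was called in each comparison, random lists cannot decide the question either. Without the list r was 0.404, but leaving out 31 of 4172 genes could hardly change r, so this value does not bear on the question.

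The stationary replicates differed more than any other pair. With all libraries thinned to 1 depth their chi-square per degree of freedom was 15.1 against 3.13 to 3.77 in the other groups. Thinning lowered this measure in every group. Lower depth could therefore not have raised it, and the thinned values could not have come out for that explanation. Without the 50 most abundant genes it was 13.6 against 3.75 to 5.63, which argues against a few abundant genes. The replicates may have been at different points of the change into stationary phase. Their difference correlated with the stationary against exponential change at r = 0.243 across 3284 genes, under the 0.3 set for this explanation. This r was above the -0.05 to 0.04 of 100 simulated pairs, but simulated genes varied independently, so that range may be too narrow for real genes. Progress and other differences between these cultures cannot be told apart with 2 libraries.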
